A study of Mus musculus with 40 samples.

How the data were processed

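Bone-marrow progenitors from C57BL6/J mice, depleted with antibodies to markers of mature T, B, NK, erythroid (TER-119), granulocyte, macrophage and dendritic cells, were grown on OP9 stroma presenting the Notch ligand DLL1 or DLL4 with IL-7 and Flt3L. Per the labels, the samples carried guides named sgCont, sgNotch1, sgNotch2, sgNotch3, sgNotch1+2 or sgNotch1+3. Phase1 cells precede T-lineage commitment and Phase2 cells follow it. The series held 40 samples: 32 RNA-seq libraries in 16 groups of 2, and 4 Rbpj ChIP-seq and 4 input libraries. Total RNA was made into libraries with the NEBNext Ultra kit and sequenced on a HiSeq2500 as single reads of 50 nt, and the labels do not state strandedness. The guides act on DNA, so RNA of a targeted gene can stay level where its protein is lost.

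The labels number the replicates and do not say whether replicates came from separate animals or cultures, so every p-value here measures spread between these samples. With 2 libraries per group no outlier test was run. The RNA libraries stood in 3 tables, Phase1 on DLL1 (6 guides), Phase2 on DLL1 (6 guides) and Phase1 on DLL4 (4 guides), each with 24506 gene entries. The values are RPKM, per the file headers, and were analyzed as log2(RPKM + 1). Each table also holds log2 fold changes and adjusted p-values from the authors' own comparisons, and these are cited only as the authors' deposited table. In the table for DLL4, 26 gene symbols had been turned into dates and were restored through their identifiers.

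Within each library 91.7–93.9% of low values, those of up to 20 reads, lay within 0.1 of a read of a whole multiple of a single step, which gave 24.7–48.6 M (mega) reads per library, of which 19.8–35.7 M fell in genes. By table the depth ran 27.0–48.6 M in Phase1 on DLL1, 30.0–47.7 M in Phase1 on DLL4 and 24.7–36.4 M in Phase2 on DLL1. Libraries detected 13207–16125 genes above 0 and 10541–11238 genes at 1 RPKM or more, and the 10 highest genes took 3.39–5.74% of reads. These step-based reads are approximate and served only for depth and for voom.

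Before the data were examined, the plan named a count-based test for count tables and the trend method of limma for tables in a normalized unit. The tables hold RPKM, so the limma trend method was used. Genes at 1 RPKM or more in at least 2 libraries of a table were kept, which left 11561 genes in Phase1 on DLL1, 11665 in Phase2 on DLL1 and 11659 in Phase1 on DLL4. A single fit per table with a mean for each guide group gave limma's moderated test, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all kept genes. Because 1 is added before taking logs, log2 fold changes understate differences of genes at low RPKM. The planned comparisons were every guide against sgCont, sgNotch1+2 and sgNotch1+3 against sgNotch1, and tests of whether sgNotch1+2 departed from the sum of the sgNotch1 and sgNotch2 effects on the log2 scale. The plan also held 8 comparisons across tables. The 3 tables were normalized separately and held no counts, so those 8 were not tested and only levels are given.

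Whether replicate numbers pair libraries was checked by correlating, between guide groups, the difference of replicate 1 from replicate 2 over all kept genes. The 15 group pairs of Phase1 on DLL1 gave correlations of 0.51–0.73 (median 0.65) and the 15 of Phase2 on DLL1 gave 0.50–0.82 (median 0.67). The labels only number the replicates, so pairing in these 2 tables rests on the data, and the main test leaves it out. The main test then counts the shared replicate difference as spread, which makes it cautious in these 2 tables. Few or no calls there do not show that a guide had no effect. A second fit with the replicate number as a block is quoted beside a result in these tables where it changes a call or moves a count by more than 1.5 times.

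Before the data were examined, 15 gene lists were fixed from general knowledge: Notch target genes, Notch pathway components, T-lineage specification, Phase 1 progenitor regulators, B-lineage, myeloid, dendritic cell, NK and innate lymphoid, erythroid/megakaryocyte/mast/basophil, OP9 stromal, cell cycle, ribosome biogenesis, interferon response, immediate early and stress, and p53 response. Il2ra, Tcf7, Gata3, Ptcra and Cd3e stand on both the Notch target and T-lineage lists, and Notch3 stands on both the Notch target and pathway lists. Lists were tested with camera in limma on the moderated statistics, with a preset correlation between genes of 0.01, adjusted over the 15 lists, and again with the correlation estimated from the data. The preset value assumes nearly independent genes, and both adjusted p-values are given for each described list that passed with the preset one. Of 195 list tests against sgCont 86 passed with the preset value, and not all of these are described. Lists of the DLL1 sets that passed only with the replicate block did not pass in that fit with an estimated correlation. For each list the genes past the test over all genes are counted, and beside them those past it adjusted over the list alone.

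Genes are named by a fixed rule. Notch1, Notch2 and Notch3 are given for every group. For each described list names are drawn from up to 4 genes past the test with the largest changes, preferring genes whose libraries separate between groups. The 5 largest rises and 5 largest falls of a comparison are named where the higher group averaged at least 5 RPKM and the libraries separated, passing over predicted genes, Rik clones, ribosomal-protein genes and pseudogenes. For lists with no gene past the test, up to 2 of the highest-expressed members are given as values only. Genes outside this rule are said to be chosen after the values were seen. Values are mean ± SD of RPKM over n = 2 libraries unless each library is given, and log2 fold changes carry ± standard errors. Copies of the beta-globin, alpha-globin, Khdc1, Ly6c and Mir7676 genes share sequence, so reads may be shared among them and the values of single copies are uncertain.

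The Rbpj ChIP-seq samples came with 2 peak lists, for Phase1 and Phase2 on DLL1, holding position, score and nearest gene. The score is the authors' own, per the file headers, and how replicates and inputs entered the peak calls is not given in the sources used here. Peaks sharing at least 1 bp were counted as shared, and proportions carry Wilson 95% intervals, which cover counting error only. Genes that rose or fell with sgNotch1+2 were compared with the remaining tested genes for having a peak assigned to them, by two-sided Fisher's exact tests adjusted over 4 tests. The 5 highest-scoring peaks of each list are given, peaks assigned to the receptors and to Notch targets are given with positions, and other genes drawn for naming that had an assigned peak are listed by name.

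Positions are on mm10: 98.7% of 23648 gene entries overlapped the gene of the same name in the mouse RefSeq reference on that build, and 92.0% of Phase1 and 98.8% of Phase2 promoter peaks lay within 2 kb of their named gene. The submitters' notes name mm9, NCBIM37 and mm10 without saying which step used which build. Per the submitters' notes, Bowtie 1.1.1, Trimmomatic 033, STAR 2.4.0, RSEM 1.2.25 and HOMER were used on reads and peaks. The authors' RNA comparisons used edgeR 3.6.8. Which tool gave the RPKM values is not stated here.

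In a self-test on simulated values with the spread of each table, up to 200 genes were shifted between sgNotch1+2 and sgCont. At a log2 change of 1 the test found 80.8% of them in Phase1 on DLL1, 53% in Phase2 on DLL1 and 37% in Phase1 on DLL4, and at 2 it found 90%, 89% and 86%. With the replicate block the values at 1 in the DLL1 sets were 91.9% and 90%. Unshifted genes were 14 of 221 calls with the block against 2 of 189 without it in Phase1 on DLL1. In Phase2 on DLL1 they were 8 of 215 against 1 of 155. A threshold of 0.05 on adjusted p allows a share of about 0.05 of calls to be unshifted genes. These counts therefore do not show that the block called too many. They do not test the block either, because the simulation gave every group the same replicate difference, taken from the fit with the block. The gain with the block was thus built in. In the real DLL1 sets that difference was correlated between groups but not identical. A comparison without shifts gave 0 calls. A shifted list of 20 further genes, which the calls include and the percentages leave out, was found by camera and an unshifted list was not. Genes varied independently in the simulation, so it does not test camera on lists of correlated genes. Of 200 peaks made to overlap, 200 were found. Analyses ran in R 4.3.3 with limma 3.58.1, in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and with bedtools 2.31.1.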

Results

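RNA was measured in mouse progenitors cultured on OP9 stroma presenting a Notch ligand. The libraries formed 3 sets, Phase1 cells on DLL1 with 6 guides, Phase2 cells on DLL1 with 6 guides and Phase1 cells on DLL4 with 4 guides, each guide with 2 libraries. Depth as the values show it was 24.7–48.6 M (mega) reads per library. Rbpj, the DNA-binding partner of cut Notch, was mapped by ChIP-seq in Phase1 and Phase2 cells on DLL1 with 2 libraries and 2 inputs each. Means are given ± SD with n = 2 libraries, and gene positions are on mm10.

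Notch receptors bind ligand on neighboring cells and are cut to free a part that joins Rbpj at target genes, and the guides were directed at Notch1, Notch2 and Notch3. In Phase1 cells on DLL1, Notch1 RNA (chromosome 2, 26457902–26503822) was the most abundant of the 3 receptors in sgCont at 31.9 ± 3.35 RPKM. It stood at 13.8 ± 2.6 with sgNotch1 (log2 change -1.16 ± 0.17, adjusted p = 0.0956, or 0.0173 with the replicate block) and at 21.8 ± 5.55 with sgNotch2 (-0.55, adjusted p = 0.239, or 0.0473 with the block). Notch1 fell to 6.79 ± 0.515 with sgNotch1+2 (adjusted p = 0.000213) and to 12.7 ± 0.254 with sgNotch1+3 (adjusted p = 0.0343), and was 33.5 ± 0.529 with sgNotch3. Notch2 (chromosome 3, 98013538–98150367) was 9.59 ± 0.617 in sgCont, 7.98 ± 0.963 with sgNotch2 (adjusted p = 0.517) and 10.5 ± 2.0 with sgNotch1+2, so its RNA does not check the sgNotch2 guide. Notch3 (chromosome 17, 32120893–32166852) was 1.15 and 1.82 RPKM in the sgCont libraries and 0.602 ± 0.0608 with sgNotch3 (log2 change -0.62, not past the test), and it fell to 0.349 ± 0.0106 with sgNotch1+2 (adjusted p = 0.0106).

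In Phase2 cells on DLL1, Notch1 was 111 ± 46.3 RPKM in sgCont (78.3 and 144 in its libraries), 56.3 ± 18.5 with sgNotch1, 49.8 ± 3.41 with sgNotch1+2 (adjusted p = 0.233, or 0.00379 with the block) and 40.5 and 65.4 in the libraries of sgNotch1+3 (adjusted p = 0.627, or 0.0216 with the block). Notch2 was 6.26 ± 0.342 in sgCont and 4.12 ± 0.479 with sgNotch2, not past the test. Notch3 was 19.9 ± 5.16 in sgCont, 8.57 ± 0.602 with sgNotch1, 11.2 ± 2.32 with sgNotch3 and 4.67 ± 1.05 with sgNotch1+3 (adjusted p = 0.155, or 0.00907 with the block), and it fell to 4.23 ± 0.654 with sgNotch1+2 (adjusted p = 0.0217). In Phase1 cells on DLL4, Notch1 was 31.3 ± 9.79 in sgCont and fell to 13.2 ± 1.77 with sgNotch1 (adjusted p = 0.0257) and 9.26 ± 1.08 with sgNotch1+2 (adjusted p = 0.00123). Notch2 was 5.71 ± 1.16 in sgCont and 4.84 ± 1.13 with sgNotch2 (adjusted p = 0.84). Notch3 was 2.86 ± 1.01 in sgCont and 0.72 ± 0.0629 with sgNotch1 (adjusted p = 0.08), and it fell to 0.322 ± 0.0863 with sgNotch1+2 (adjusted p = 0.00787).

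**Figure D1:**
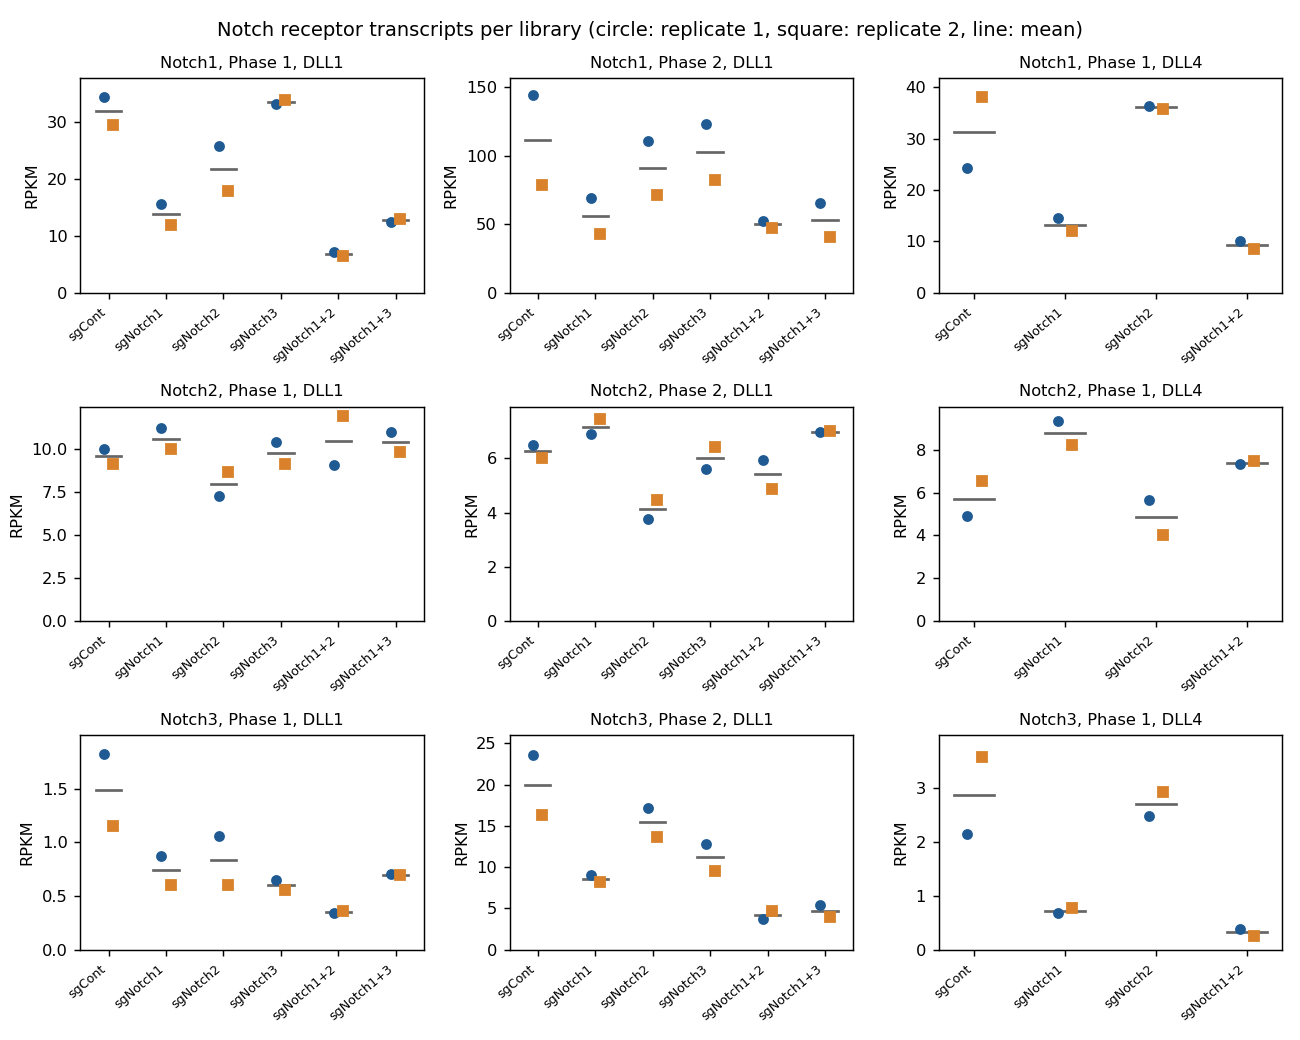
RPKM of Notch1, Notch2 and Notch3 in every RNA library of the 3 sets, by guide (circle, replicate 1, square, replicate 2, line, mean). Notch1 was lower in both sgNotch1+2 libraries than in both sgCont libraries of each set, and Notch2 did not pass the test with sgNotch2 in any set, at 3.78 and 4.46 RPKM against 6.5 and 6.02 in sgCont in Phase2.

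The guide against Notch1 alone asked what Notch1 contributes before commitment on DLL1. Few genes fell: Dtx1, a direct Notch target that encodes a ubiquitin ligase, Mdfi, which encodes an inhibitor of myogenic transcription factors, Fbp1, a gluconeogenic enzyme gene, Deptor, which encodes an inhibitor of mTOR, and Gpr132, a G-protein-coupled receptor gene. Il2ra, the CD25 marker gene of T-lineage progress, and Tcf7, an early T-lineage regulator, did not pass the test. The test called 5 of 11561 genes, 0 of them rising (684 at an unadjusted p below 0.05). Dtx1 (chromosome 5, 120680264–120711669) fell from 20.2 ± 0.51 to 2.88 ± 0.87 RPKM (log2 -2.47 ± 0.25), Mdfi from 16.8 to 3.6 (-1.95 ± 0.23), Fbp1 from 7.42 to 1.21 (-1.94 ± 0.22), Deptor from 8.16 to 2.01 (-1.6 ± 0.17) and Gpr132 from 13.9 to 6.33 (-1.01 ± 0.12), each at an adjusted p of 0.0495. Il2ra was 156 ± 16.4 against 243 ± 2.62 (adjusted p = 0.886) and Tcf7 was 183 against 175. With the block 86 genes passed (52 rose, 34 fell) and with a pseudocount of 5 there were 9, but voom, a pseudocount of 0.1 and no filter each gave 0. Removing sgCont replicate 1, sgCont replicate 2, sgNotch1 replicate 1 or sgNotch1 replicate 2 left 0.

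As sets in these sgNotch1 cells, Notch targets lay lower, T-lineage genes slightly so (median -0.03), and myeloid genes, which mark granulocyte and monocyte fates, lay higher. Of 11 Notch target genes 1 fell (3 adjusted over the list alone; camera adjusted p = 1.21e-05, adjusted p = 0.139 with an estimated correlation). Of 24 T-lineage genes 0 changed (3 fell adjusted over the list alone, 1 with the block; camera adjusted p = 0.00974, adjusted p = 0.557 with an estimated correlation). All 19 myeloid genes had positive changes with a median of 0.61, and 0 passed the test (1 rose adjusted over the list alone, 2 with the block; camera adjusted p = 2.58e-06, adjusted p = 0.139 with an estimated correlation). Of 14 p53-response genes 14 were positive and 0 passed (1 adjusted over the list alone, 1 with the block; camera adjusted p = 1.53e-05, adjusted p = 0.139 with an estimated correlation). The immediate early list had a camera adjusted p of 0.214, or 0.0143 with the block.

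The guide against Notch2 alone asked whether Notch2 has a part of its own in Phase1 cells on DLL1. Ms4a3, a marker of granulocyte-monocyte progenitors, Csf2rb, the shared receptor chain gene for GM-CSF, IL-3 and IL-5, and 2 genes of the myeloid list, the monocyte chemokine-receptor gene Ccr2 and the Fc-receptor gene Fcgr3, rose. The Notch target Dtx1 fell, as did Pdgfrb, a receptor gene on the stromal list, and Tsc22d1, a transcription-regulator gene. The test called 41 genes (34 rose, 7 fell). Ms4a3 (chromosome 19, 11629499–11640851) rose from 15.2 ± 1.81 to 73.7 ± 21.7 RPKM (log2 2.18 ± 0.22, adjusted p = 0.0278), Csf2rb (chromosome 15, 78325990–78351001) from 16.0 ± 1.23 to 50.2 ± 5.58 (1.58 ± 0.19, adjusted p = 0.0278) and Ccr2 (chromosome 9, 124102183–124109140) from 39.1 ± 3.54 to 111 ± 24.9 (1.46 ± 0.21, adjusted p = 0.0434). Slpi, a secreted protease-inhibitor gene of myeloid cells, rose by 1.93 ± 0.28 (adjusted p = 0.0434), and both copies of Mir7676 rose but share sequence. Dtx1 fell to 5.06 ± 1.0 (-1.82 ± 0.25, adjusted p = 0.0391), Pdgfrb from 14.3 to 6.03 (-1.13, adjusted p = 0.0412), Bcl2l14 by -0.99 (adjusted p = 0.0452) and Tsc22d1 by -0.93 (adjusted p = 0.0278). With the block 694 genes passed (531 rose, 163 fell), with voom 23, with median-ratio scaling 19 and without the filter 1. Leaving out sgCont replicate 1, sgCont replicate 2 or sgNotch2 replicate 2 left 0, and leaving out sgNotch2 replicate 1 gave 59.

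For sgNotch2, of 19 myeloid genes 2 rose (10 adjusted over the list alone, 12 with the block), with a median of 1.06 and 18 positive (camera adjusted p = 5.54e-08, adjusted p = 0.196 with an estimated correlation). Of 11 Notch target genes 1 fell (1 adjusted over the list alone; camera adjusted p = 2.7e-05, adjusted p = 0.196 with an estimated correlation). Of 24 T-lineage genes 0 changed (5 fell adjusted over the list alone, 3 with the block), with a median of -0.34 (camera adjusted p = 2.7e-05, adjusted p = 0.37 with an estimated correlation). Of 18 interferon-response genes 0 changed (1 fell adjusted over the list alone, 5 with the block; camera adjusted p = 4.19e-05, adjusted p = 0.407 with an estimated correlation). The Phase 1 progenitor list had a camera adjusted p of 0.0366 (0.169 with the block, adjusted p = 0.309 with an estimated correlation).

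The guide against Notch3 asked whether this receptor contributes in Phase1 on DLL1, and no gene passed the test. Limma called 0 genes (143 at an unadjusted p below 0.05), voom on approximate reads called 0 and the fit with the block called 0. Il2ra was 287 RPKM against 243 and Tcf7 was 193 against 175. The immediate early list shifted down with a median of -0.47 (camera adjusted p = 8.64e-05, adjusted p = 0.521 with an estimated correlation) with 0 of 16 genes past the test. The stromal list had a median of -0.45 (camera adjusted p = 0.123, or 0.000201 with the block).

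The pair of guides against Notch1 and Notch2 asked what is left of the T-cell program in Phase1 on DLL1 when both receptors are targeted. Of the T-lineage genes 15 of 24 fell. Genes that fell included Il2ra, the Notch targets Dtx1, Nrarp and Hes1, the early regulator Tcf7, the kinase gene Lck of T-cell receptor signaling and Cd3g, a T-cell receptor subunit gene. Of the myeloid genes 15 of 19 rose, among them Mpo and Elane, which encode granule enzymes of neutrophil progenitors, and Ly6c2, a monocyte surface gene. The stem and progenitor gene Lmo2 rose, while Erg, Mycn and Cd34 of the same progenitor list fell. Gzma, an effector granzyme gene, and the beta-globin genes also fell. The test called 2971 of 11561 genes (1529 rose, 1442 fell), of which 431 rose and 315 fell at least 2-fold. With the block 4800 passed (2369 rose, 2431 fell). Leaving out sgCont replicate 1 gave 1428, sgCont replicate 2 gave 1519 and sgNotch1+2 replicate 2 gave 1813.

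Il2ra (chromosome 2, 11642792–11693194) fell from 243 ± 2.62 to 6.39 ± 3.76 RPKM with sgNotch1+2 (log2 -5.15 ± 0.32, adjusted p = 0.000104). Dtx1 fell from 20.2 ± 0.51 to 0.0545 (-4.33 ± 0.25, adjusted p = 7.82e-05), Nrarp from 19.7 to 1.52 (-3.19 ± 0.39, adjusted p = 0.00107) and Hes1 (chromosome 16, 30065357–30067796) from 19.2 to 3.04 (-2.55 ± 0.44, adjusted p = 0.00451). Tcf7 (chromosome 11, 52252283–52283014) fell from 175 ± 17.1 to 36.0 ± 26.8 (-2.47 ± 0.46, adjusted p = 0.00669), and Cd3g fell by -2.37 ± 0.22 (adjusted p = 0.000371). Mpo (chromosome 11, 87793784–87804412) rose from 48.7 ± 10.4 to 505 ± 172 (3.32 ± 0.28, adjusted p = 0.000256), Elane from 22.4 ± 8.01 to 222 ± 3.14 (3.3 ± 0.37, adjusted p = 0.000779) and Ly6c2 from 16.6 ± 5.95 to 555 ± 302 (4.91 ± 0.55, adjusted p = 0.000764), with reads that Ly6c1 may share. Gzma (chromosome 13, 113093824–113100981) fell from 542 to 24.3 (-4.77 ± 0.55, adjusted p = 0.000796) and Lmo2 rose from 26.4 to 90.3 (1.72 ± 0.23, adjusted p = 0.00143). Other large rises past the test were Ms4a3 (15.2 to 246 RPKM), Slpi (1.47 to 36.2) and F13a1 (1.92 to 39.7), and other large falls were Khdc1c, Khdc1a and the beta-globin genes, whose copies share sequence.

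For sgNotch1+2 in Phase1 on DLL1, of 11 Notch target genes 9 fell (10 adjusted over the list alone), with a median of -1.52 (camera adjusted p = 3.41e-06, adjusted p = 0.139 with an estimated correlation). Of 24 T-lineage genes 15 fell (15 adjusted over the list alone, 18 with the block), with a median of -1.5 (camera adjusted p = 2.58e-07, adjusted p = 0.361 with an estimated correlation). Of 19 myeloid genes 15 rose (16 adjusted over the list alone, 17 with the block), with a median of 2.23 (camera adjusted p = 4.16e-09, adjusted p = 0.139 with an estimated correlation). Of 16 NK and innate lymphoid genes 6 rose and Gzma fell (10 rose adjusted over the list alone, 10 rose and 2 fell with the block; camera adjusted p = 0.00436, adjusted p = 0.629 with an estimated correlation). Il2rb, a receptor gene for IL-2 and IL-15, Eomes, a regulator of NK cells, and Klrd1, an NK receptor gene, were among those that rose. Of 14 p53-response genes 8 rose (9 adjusted over the list alone, 10 rose and 1 fell with the block; camera adjusted p = 0.00122, adjusted p = 0.361 with an estimated correlation), with Fas, Bbc3, Zmat3 and Ccng1 among them.

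The other lists of this comparison moved less as sets. Of 19 progenitor regulators 3 rose and 7 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.118), and of 21 Notch pathway genes 6 rose and 5 fell (camera adjusted p = 0.609), with Psen2 up and Maml3 down. Of 11 B-lineage genes 1 rose (Bst1) and 2 fell (Blk and Cd22; camera adjusted p = 0.89). Of 10 dendritic-cell genes Irf8 rose from 24.9 to 67.3 RPKM and Itgax fell from 9.29 to 0.758 (camera adjusted p = 0.923). The B-lineage and dendritic lists had medians of 0.08 and 0.06 and means of -0.11 and -0.07, so their medians and means differed in sign. Of 17 erythroid, megakaryocyte, mast and basophil genes 2 fell, both beta-globin, and the list had a median of 0.58 and a mean of -0.18 (camera adjusted p = 0.608). Mast-cell and basophil genes differed between the replicates, with Cpa3 at 456 RPKM in sgNotch1+2 replicate 1 and 21.0 in replicate 2. Of 13 stromal genes Thbs1 rose and Pdgfrb fell (camera adjusted p = 0.587), and of 22 cell-cycle genes 5 rose and 4 fell (9 and 6 with the block; camera adjusted p = 0.245). Of 18 ribosome-biogenesis genes 2 fell (Wdr12 and Polr1b; camera adjusted p = 0.0231, adjusted p = 0.445 with an estimated correlation). Of 18 interferon genes 5 fell (10 fell and 2 rose with the block; camera adjusted p = 0.062, or 0.00477 with the block), with Rtp4, Isg15, Oas2 and Irf7 among them. Of 16 immediate early genes Atf3 rose (8 rose and 2 fell with the block; camera adjusted p = 0.185).

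**Figure D2:**
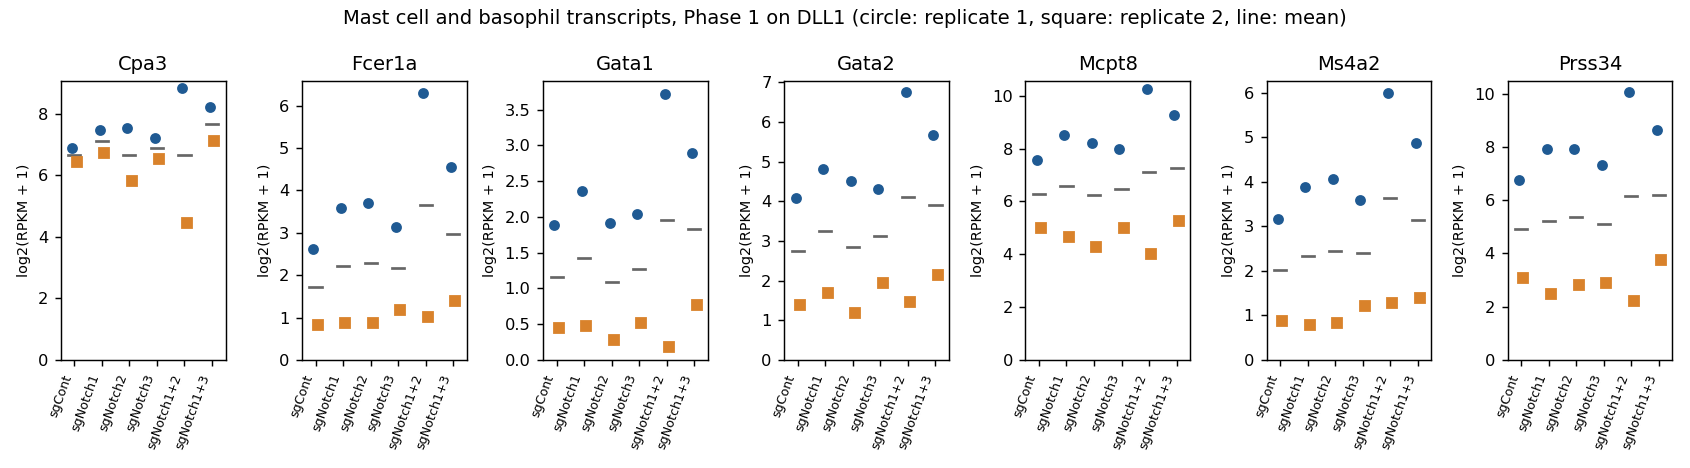
log2(RPKM + 1) of 7 mast-cell and basophil genes in each library of Phase1 cells on DLL1, by guide (circle, replicate 1, square, replicate 2, line, mean). Replicate 1 lay above replicate 2 in each panel, and with sgNotch1+2 the Fcer1a RPKM was 78.3 in replicate 1 and 1.02 in replicate 2.

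**Figure D3:**
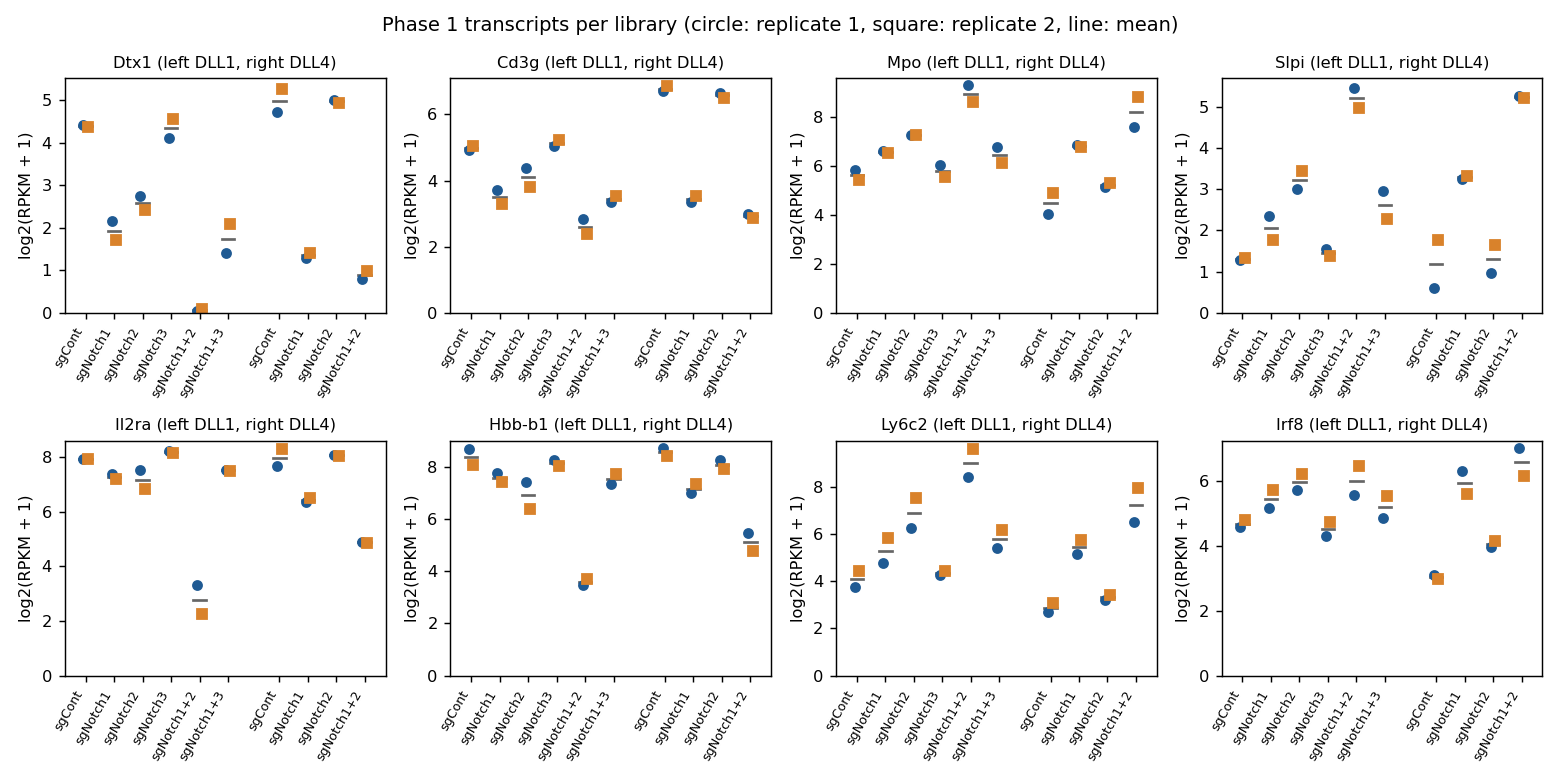
log2(RPKM + 1) of 8 named genes in each library of Phase1 cells on DLL1 (left) and DLL4 (right), by guide (circle, replicate 1, square, replicate 2, line, mean). Il2ra and Dtx1 were lowest and Mpo was highest with sgNotch1+2 in both sets.

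The guides against Notch1 and Notch3 together asked whether Notch3 adds to Notch1 in Phase1 on DLL1. The Notch target Dtx1 fell, with Mdfi, Fbp1, Deptor, the T-cell receptor gene Cd3g and the progenitor regulator Lyl1, and Ms4a3 and the Fc-receptor gene Fcgr3, the latter from the myeloid list, rose. The test called 27 genes (13 rose, 14 fell; 1033 at an unadjusted p below 0.05). Dtx1 fell to 2.45 RPKM (log2 -2.66 ± 0.25, adjusted p = 0.0275), Cd3g from 30.5 to 9.91 (-1.53 ± 0.22, adjusted p = 0.0459) and Lyl1 by -0.78 (adjusted p = 0.0337). Ms4a3 rose by 1.77 ± 0.22 (adjusted p = 0.0337) and Fcgr3 by 1.28 ± 0.17 (adjusted p = 0.0343). Ramp3 (2.04), Xdh (1.33) and Nfil3 (1.0) rose as well, and Khdc1a fell (-1.66). With the block 238 genes passed (165 rose, 73 fell), with a pseudocount of 5 there were 41 and without the filter 0, and leaving out sgCont replicate 1, sgCont replicate 2, sgNotch1+3 replicate 1 or sgNotch1+3 replicate 2 left 0.

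For sgNotch1+3, of 11 Notch target genes 1 fell (4 adjusted over the list alone, 2 with the block; camera adjusted p = 7.46e-06, adjusted p = 0.103 with an estimated correlation). Of 19 myeloid genes 1 rose (2 adjusted over the list alone, 5 with the block; camera adjusted p = 1.6e-06, adjusted p = 0.127 with an estimated correlation) and of 16 NK genes 1 rose (5 adjusted over the list alone, 4 with the block; camera adjusted p = 1.51e-06, adjusted p = 0.283 with an estimated correlation). Of 19 progenitor regulators 1 fell (3 adjusted over the list alone, 6 with the block; camera adjusted p = 0.000314, adjusted p = 0.103 with an estimated correlation). The interferon list had a camera adjusted p of 0.238, or 0.0436 with the block, and the immediate early list 0.538, or 0.0329 with the block. Against sgNotch1 alone, limma called 0 genes for sgNotch1+3 (253 at an unadjusted p below 0.05, 0 by voom and 0 with the block). Il2ra was 182 RPKM against 156 and Tcf7 was 201 against 183.

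Set against sgNotch1 alone, sgNotch1+2 asked what the Notch2 guide adds in Phase1 on DLL1. Relative to sgNotch1 alone, the added guide lowered the T-lineage genes Il2ra, Tcf7, Lck and Ly6d, a lymphoid progenitor surface gene, and raised the granulocyte genes Mpo, Elane and Ctsg. Notch1 itself fell further (log2 -0.92, adjusted p = 0.0106). The test called 2033 genes (936 rose, 1097 fell), 210 rising and 228 falling at least 2-fold, and the balance depended on the method (1062 rose and 985 fell with median-ratio scaling, 812 and 1316 with voom). Il2ra fell from 156 ± 16.4 to 6.39 ± 3.76 RPKM (-4.5 ± 0.32, adjusted p = 0.000637), and Tcf7 by -2.52, Lck by -2.61, Ly6d by -3.19, Hes1 by -2.33 and Gzma by -4.17. Mpo rose from 92.7 to 505 (2.39), Elane by 2.47, Ctsg by 2.39, Slpi by 3.14, F13a1 by 2.97, Slc16a3 by 2.95, Ly6c2 by 3.71 and Ly6c1 by 3.05, and the beta-globin genes fell (Hbb-b2 by -4.37). Of 24 T-lineage genes 11 fell (15 adjusted over the list alone, 18 with the block; camera adjusted p = 1.02e-07, adjusted p = 0.339 with an estimated correlation). Of 19 myeloid genes 10 rose (14 adjusted over the list alone, 16 with the block; camera adjusted p = 3.49e-08, adjusted p = 0.286 with an estimated correlation). With the block 3962 genes passed (1785 rose, 2177 fell), and leaving out sgNotch1 replicate 1 gave 650, sgNotch1 replicate 2 gave 973 and sgNotch1+2 replicate 2 gave 915.

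Whether sgNotch1+2 departed from the sum of the single-guide effects in Phase1 on DLL1 was tested gene by gene, and no gene passed. Limma called 0 genes (1288 at an unadjusted p below 0.05), voom called 3, and the fit with the block called 202 (55 above and 147 below the sum). Leaving out sgNotch2 replicate 2 gave 24 and leaving out sgNotch1+2 replicate 1 gave 76. The T-lineage list lay below the sum with a median of -0.88 and 0 genes past the test (7 adjusted over the list alone, 6 with the block; camera adjusted p = 3.13e-05, adjusted p = 0.71 with an estimated correlation). The myeloid list lay above it (camera adjusted p = 0.00292, adjusted p = 0.71 with an estimated correlation).

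**Figure D4:**
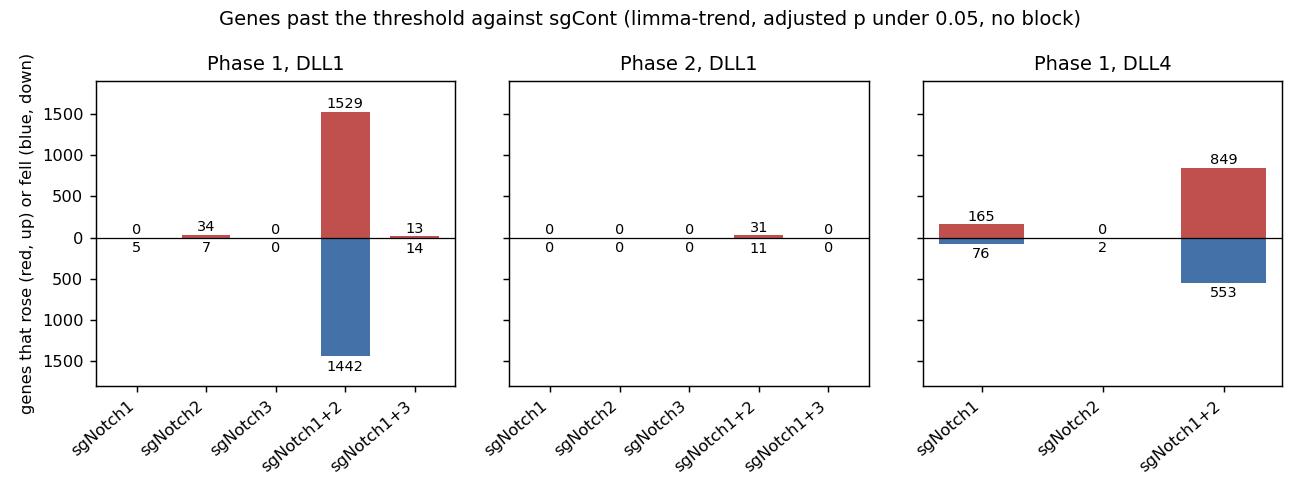
Genes that rose (upper bars) and fell (lower bars) against sgCont at an adjusted p below 0.05, by guide, in the 3 sets. With sgNotch1+2 the counts were 2971 in Phase1 on DLL1, 42 in Phase2 on DLL1 and 1402 in Phase1 on DLL4, and with the replicate block, not drawn, they were 4800 and 4143 in Phase1 and Phase2 on DLL1.

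On DLL4, a ligand that binds Notch1 strongly, the sgNotch1 guide asked how far Phase1 cells depend on Notch1. The Notch targets Dtx1 and Nrarp and the T-cell receptor genes Cd3g, Cd3e and Cd3d fell, and so did Il2ra and Gzma. Irf8, a regulator of monocyte and dendritic fates, rose with the macrophage gene Mpeg1 and the granule enzyme genes Prtn3 and Mpo. Of 19 progenitor regulators Flt3, Mef2c, Lmo2 and Spi1 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.465). The test called 241 of 11659 genes (165 rose, 76 fell), 108 rising and 49 falling at least 2-fold, and with median-ratio scaling the split was 122 and 98. Dtx1 fell from 31.5 to 1.55 RPKM (log2 -3.65 ± 0.2, adjusted p = 8.1e-05), Cd3g (chromosome 9, 44969572–44980431) from 109 ± 8.71 to 9.92 ± 1.01 (-3.33 ± 0.13, adjusted p = 1.02e-05) and Il2ra from 257 ± 74.9 to 84.9 ± 6.64 (-1.56, adjusted p = 0.00357). Irf8 (chromosome 8, 120736358–120756692) rose from 7.19 to 62.9 (2.93 ± 0.29, adjusted p = 0.00172), Prtn3 from 19.3 to 147 (2.86, adjusted p = 0.000217), and Mpo from 22.03 to 111 (2.34). Mpeg1 rose by 2.91, Ms4a3 by 2.82, Ms4a6c by 2.67 and Ly6c2 by 2.58, and Fbp1 fell by -3.16, Khdc1c by -2.96 and Khdc1a by -2.91. Without the filter 55 genes passed. Leaving out sgCont replicate 1 gave 50, sgCont replicate 2 gave 114, sgNotch1 replicate 1 gave 42 and sgNotch1 replicate 2 gave 30.

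For sgNotch1 on DLL4, of 12 Notch target genes 4 fell and 1 rose (6 and 1 adjusted over the list alone; camera adjusted p = 2.14e-08, adjusted p = 0.152 with an estimated correlation). Of 25 T-lineage genes 5 fell and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p = 8.58e-08, adjusted p = 0.152 with an estimated correlation). Of 20 myeloid genes 6 rose (13 adjusted over the list alone), with a median of 1.24 (camera adjusted p = 2.81e-11, adjusted p = 0.176 with an estimated correlation). Of 15 NK genes 4 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.000715, adjusted p = 0.187 with an estimated correlation). Of 13 p53-response genes 2 rose, Pmaip1 and Ccng1 (6 adjusted over the list alone; camera adjusted p = 3.89e-05, adjusted p = 0.152 with an estimated correlation).

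The sgNotch2 guide alone asked whether Notch2 has a part on DLL4, and 2 microRNA genes fell. Limma called 2 genes (0 rose, 2 fell; 657 at an unadjusted p below 0.05), Mir5136 (log2 -3.27, adjusted p = 0.0407) and Mir5122 (-3.05, adjusted p = 0.0145), both listed at 0 in the 2 sgNotch2 libraries. Voom, a pseudocount of 5 and no filter each gave 0 calls, median-ratio scaling gave 1 and a pseudocount of 0.1 gave 4. Mir5136 was 5.88 and 12.6 RPKM in the sgCont libraries. Genes this short gather few reads at a given RPKM. In the self-test, 37% of genes shifted by a log2 change of 1 were found on DLL4. Few calls here therefore do not show that the guide had no effect. Irf8 was 15.7 against 7.19 (1.03, adjusted p = 0.81) and Il2ra was 267 against 257. Of 20 myeloid genes 0 passed (3 rose adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0199, adjusted p = 0.985 with an estimated correlation), and the other 14 lists did not pass camera. Leaving out sgCont replicate 1 gave 1, sgNotch2 replicate 1 gave 117 and sgNotch2 replicate 2 gave 0.

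With sgNotch1+2 on DLL4, 15 of 25 T-lineage genes fell, and 14 of 20 myeloid and 4 of 11 dendritic-cell genes rose. Cd3g, Cd3e, Il2ra, Dtx1, Nrarp and Rag2, a gene for cutting receptor loci, fell with Gzma and the beta-globin genes. Prtn3, Mpo, Irf8, Ly6c2 and the dendritic-cell genes Siglech, Cd74 and Batf3 rose, and of 19 progenitor regulators 6 rose, with Flt3, Lmo2 and Mef2c among them, and 5 fell, with Erg among them (7 and 6 adjusted over the list alone; camera adjusted p = 0.75). The test called 1402 genes (849 rose, 553 fell), 452 rising and 256 falling at least 2-fold. Cd3g fell from 109 ± 8.71 to 6.61 RPKM (log2 -3.85 ± 0.13, adjusted p = 1.43e-06), Il2ra from 257 ± 74.9 to 28.3 (-3.11 ± 0.17, adjusted p = 2.34e-05) and Dtx1 from 31.5 to 0.866 (-4.1 ± 0.2, adjusted p = 1.51e-05). Prtn3 rose from 19.3 to 315 (3.94, adjusted p = 1.51e-05), Irf8 from 7.19 to 100.3 (3.57, adjusted p = 0.000124) and Mpo from 22.03 to 318 ± 185 (3.72, adjusted p = 0.000336). Olfm1 (4.31), Mpeg1 (4.14), Slpi (4.06) and Ms4a3 (4.01) had large rises, and Fbp1 (-4.02), Khdc1a (-3.97), Khdc1c (-3.92) and Gzma (-3.73, adjusted p = 5.74e-07) had large falls. The count was 656 without sgCont replicate 1, 836 without sgNotch1+2 replicate 1 and 716 without sgNotch1+2 replicate 2.

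For sgNotch1+2 on DLL4, of 12 Notch target genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 2.9e-09, adjusted p = 0.111 with an estimated correlation), and of 25 T-lineage genes 15 fell (17 adjusted over the list alone; camera adjusted p = 5.07e-16, adjusted p = 0.111 with an estimated correlation). Of 20 myeloid genes 14 rose (18 adjusted over the list alone), with a median of 2.23 (camera adjusted p = 1.95e-13, adjusted p = 0.111 with an estimated correlation). Of 11 dendritic-cell genes 4 rose (4 adjusted over the list alone; camera adjusted p = 0.00789, adjusted p = 0.144 with an estimated correlation), and of 15 NK genes 8 rose and 3 fell (camera adjusted p = 0.00925, adjusted p = 0.272 with an estimated correlation). Of 14 immediate early genes 5 rose, with Zfp36, Jun, Trib3 and Klf6 among them (6 adjusted over the list alone; camera adjusted p = 0.00322, adjusted p = 0.111 with an estimated correlation), and of 13 p53-response genes 6 rose (7 adjusted over the list alone; camera adjusted p = 0.00174, adjusted p = 0.111 with an estimated correlation).

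Against sgNotch1 alone on DLL4, the added Notch2 guide lowered the T-lineage genes Il2ra, Tcf7, Rag2 and Lat and the Notch target Hes1, with Kit, the stem-cell-factor receptor gene, and Fgf3, a growth-factor gene. Beta-globin genes, Gzma, the mast-cell and progenitor gene Cpa3 and the megakaryocyte integrin gene Itga2b fell too. Ctsg and Prtn3, granule enzyme genes, and the myeloid inhibitor gene Slpi rose. The test called 138 genes (21 rose, 117 fell), voom 196 (66 rose, 130 fell), and the test without the filter 62 (6 rose, 56 fell). Il2ra fell from 84.9 ± 6.64 to 28.3 RPKM (log2 -1.55, adjusted p = 0.00422), Hes1 from 21.6 to 7.01 (-1.5, adjusted p = 0.00314), Tcf7 from 192 to 89.8 (-1.09) and Fgf3 from 39.5 to 9.14 (-1.99, adjusted p = 0.000815). Hbb-b2, Hbb-bt, Hbb-b1 and Hbb-bs, which share sequence, fell by -2.08 to -2.03, Gzma by -1.68, Cpa3 by -1.31 and Itga2b by -1.3. Snord1a (2.55), Mir6244 (2.45), Slpi (1.95), Lgmn (1.52), Anxa3 (1.34), Ctsg (1.24) and Prtn3 (1.08) rose. Of 25 T-lineage genes 9 fell (16 adjusted over the list alone; camera adjusted p = 2.72e-17, adjusted p = 0.104 with an estimated correlation) and of 20 myeloid genes 2 rose (9 adjusted over the list alone; camera adjusted p = 8e-12, adjusted p = 0.22 with an estimated correlation). Leaving out sgNotch1 replicate 1 gave 26, sgNotch1 replicate 2 gave 14, sgNotch1+2 replicate 1 gave 76 and sgNotch1+2 replicate 2 gave 56.

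Tested against the sum of the single-guide effects on DLL4, sgNotch1+2 departed for 15 genes, with 13 below the sum and 2 above it. Voom gave 31 (0 above the sum), a pseudocount of 0.1 gave 26 and no filter gave 0. Lck (chromosome 4, 129548344–129558372), the kinase gene of T-cell receptor signaling, lay below the sum by -1.26 (adjusted p = 0.0211), Gzma by -1.47 (adjusted p = 0.0141) and Cpa3 (chromosome 3, 20215616–20242181), a carboxypeptidase gene of mast cells and early progenitors, by -1.22 (adjusted p = 0.0141). Fgf3 lay below by -1.92 (adjusted p = 0.0141) and Angpt1, a progenitor-expressed ligand gene, by -1.57 (adjusted p = 0.0211). The 2 above the sum were the microRNA genes Mir5136 and Mir5122, and Mir8119, below it, lies within Lck. Mir8099-1 and Mir8099-2, also below it, are listed at the same position. Of 25 T-lineage genes 1 passed (12 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 4.16e-13, adjusted p = 0.171 with an estimated correlation). Leaving out sgCont replicate 1 gave 1, sgCont replicate 2 gave 26, sgNotch1 replicate 1 or 2 gave 0, sgNotch2 replicate 2 gave 5 and sgNotch1+2 replicate 1 or 2 gave 0.

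In Phase2 cells on DLL1 the single guides asked whether committed cells still depend on each receptor, and none called a gene in the fit without the block. Their counts at an unadjusted p below 0.05 were each under a 0.05 share of the genes. The replicate difference stayed in the spread of that fit, so 0 calls do not show absence of effect. For sgNotch1 limma called 0 of 11665 genes (296 at an unadjusted p below 0.05, 0 by voom, and 15 with the block, 4 rising and 11 falling). Il2ra was 140 ± 27.8 RPKM against 330 ± 42.8 in sgCont (log2 -1.24). Of 12 Notch target genes 0 passed (5 fell adjusted over the list alone, 2 with the block), with a median of -0.75 (camera adjusted p = 3.55e-11, adjusted p = 0.0145 with an estimated correlation). Of 15 myeloid genes all 15 had positive changes with a median of 1.75, and 0 passed (1 rose adjusted over the list alone; camera adjusted p = 4.43e-11, adjusted p = 0.186 with an estimated correlation). The erythroid and mast list had a camera adjusted p of 0.0965, or 0.0112 with the block. For sgNotch2 limma called 0 (31 at an unadjusted p below 0.05, 0 by voom, 0 with the block), the Notch target list shifted down with a median of -0.17 (camera adjusted p = 0.000634, adjusted p = 0.127 with an estimated correlation), and the ribosome list had a camera adjusted p of 0.0771, or 0.00194 with the block. For sgNotch3 limma called 0 (25 at an unadjusted p below 0.05, 0 by voom, 0 with the block, 1 without the filter), and the erythroid and mast list had a camera adjusted p of 0.0626, or 0.0189 with the block.

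With sgNotch1+2 in Phase2 on DLL1, few genes passed the test. Dtx1, Notch3, Cd3g, the proto-oncogene Myc and the stem-cell regulator Erg fell. Ccr2 and Ccr9, chemokine-receptor genes, Sdc4, a surface proteoglycan gene, S100a4, a calcium-binding protein gene, and Klrd1, an NK receptor gene, rose. The test called 42 genes (31 rose, 11 fell; 2128 at an unadjusted p below 0.05). Dtx1 fell from 50.0 ± 11.5 to 4.51 ± 1.96 RPKM (log2 -3.24 ± 0.29, adjusted p = 0.0171), Cd3g from 428 ± 13.2 to 148 ± 39.0 (-1.55 ± 0.23, adjusted p = 0.0392) and Myc from 66.2 to 27.6 (-1.24 ± 0.19, adjusted p = 0.041). Fbp1 fell by -2.16, Myl4 by -2.11 and Erg by -1.45. Sdc4 rose from 0.405 to 8.56 (2.77 ± 0.22, adjusted p = 0.0106), Ccr2 from 19.9 to 137 (2.62, adjusted p = 0.0316), Ccr9 from 2.21 to 18.4 (2.6), S100a4 from 35.1 to 185 (2.38), Susd2 by 2.29 and Klrd1 by 2.22 (adjusted p = 0.0423). With the block 4143 genes passed (2639 rose, 1504 fell), and without the filter 27. Leaving out sgCont replicate 1, sgCont replicate 2 or sgNotch1+2 replicate 1 left 0, and leaving out sgNotch1+2 replicate 2 left 9.

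For sgNotch1+2 in Phase2, cell-cycle genes lay lower as a set. None of the 22 was positive, the median was -1.2 and 0 passed (0 adjusted over the list alone, 19 fell with the block; camera adjusted p = 2.61e-09, adjusted p = 0.541 with an estimated correlation), with Pcna at 144 against 269 RPKM and Mcm6 at 70.5 against 149 (adjusted p = 0.227, or 0.0139 with the block). Of 12 Notch target genes 3 fell (7 fell and 1 rose adjusted over the list alone, 8 fell and 2 rose with the block; camera adjusted p = 7.04e-07, adjusted p = 0.0574 with an estimated correlation). Of 25 T-lineage genes 1 fell (7 fell and 4 rose adjusted over the list alone; camera adjusted p = 0.172), with a median of 0.06 and a mean of -0.19. Of 15 myeloid genes Ccr2 alone rose (camera adjusted p = 0.338). Of 16 NK genes 1 rose (9 adjusted over the list alone, 12 with the block; camera adjusted p = 8.57e-06, adjusted p = 0.212 with an estimated correlation), and of 13 p53-response genes Phlda3 and Ccng1 rose (6 adjusted over the list alone, 9 rose and 1 fell with the block; camera adjusted p = 0.000112, adjusted p = 0.15 with an estimated correlation). Of 18 ribosome-biogenesis genes 0 passed (15 fell and 1 rose with the block; camera adjusted p = 0.000159, adjusted p = 0.653 with an estimated correlation).

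For sgNotch1+3 in Phase2, limma called 0 genes (893 at an unadjusted p below 0.05, 0 by voom), but with the block 341 passed (271 rose, 70 fell), without the filter 4, and with a pseudocount of 5 or median-ratio scaling 1. Leaving out sgNotch1+3 replicate 2 gave 29. Il2ra was 110 RPKM against 330 (log2 -1.68, adjusted p = 0.54, or 0.0277 with the block). Of 12 Notch target genes 0 passed (7 fell and 1 rose adjusted over the list alone, 7 fell with the block), with a median of -1.06 (camera adjusted p = 9.67e-09, adjusted p = 0.0278 with an estimated correlation). None of the 22 cell-cycle genes was positive, with a median of -0.77 and 0 past the test (camera adjusted p = 3.07e-08, adjusted p = 0.47 with an estimated correlation). The dendritic-cell list had a camera adjusted p of 0.00327 (0.0686 with the block, adjusted p = 0.352 with an estimated correlation) and the interferon list had 0.0214 (0.0512 with the block, adjusted p = 0.47 with an estimated correlation). Against sgNotch1 alone, limma called 0 genes for sgNotch1+2 (762 at an unadjusted p below 0.05) and 0 for sgNotch1+3 (79), voom and the fit with the block called 0 for both, the test without the filter called 1 and 3, and the cell-cycle list lay lower with sgNotch1+2 (median -1.14, camera adjusted p = 4.51e-12, adjusted p = 0.401 with an estimated correlation). Departure from the sum of the single-guide effects passed for 0 genes (151 at an unadjusted p below 0.05, 0 by voom, 0 with the block).

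**Figure D5:**
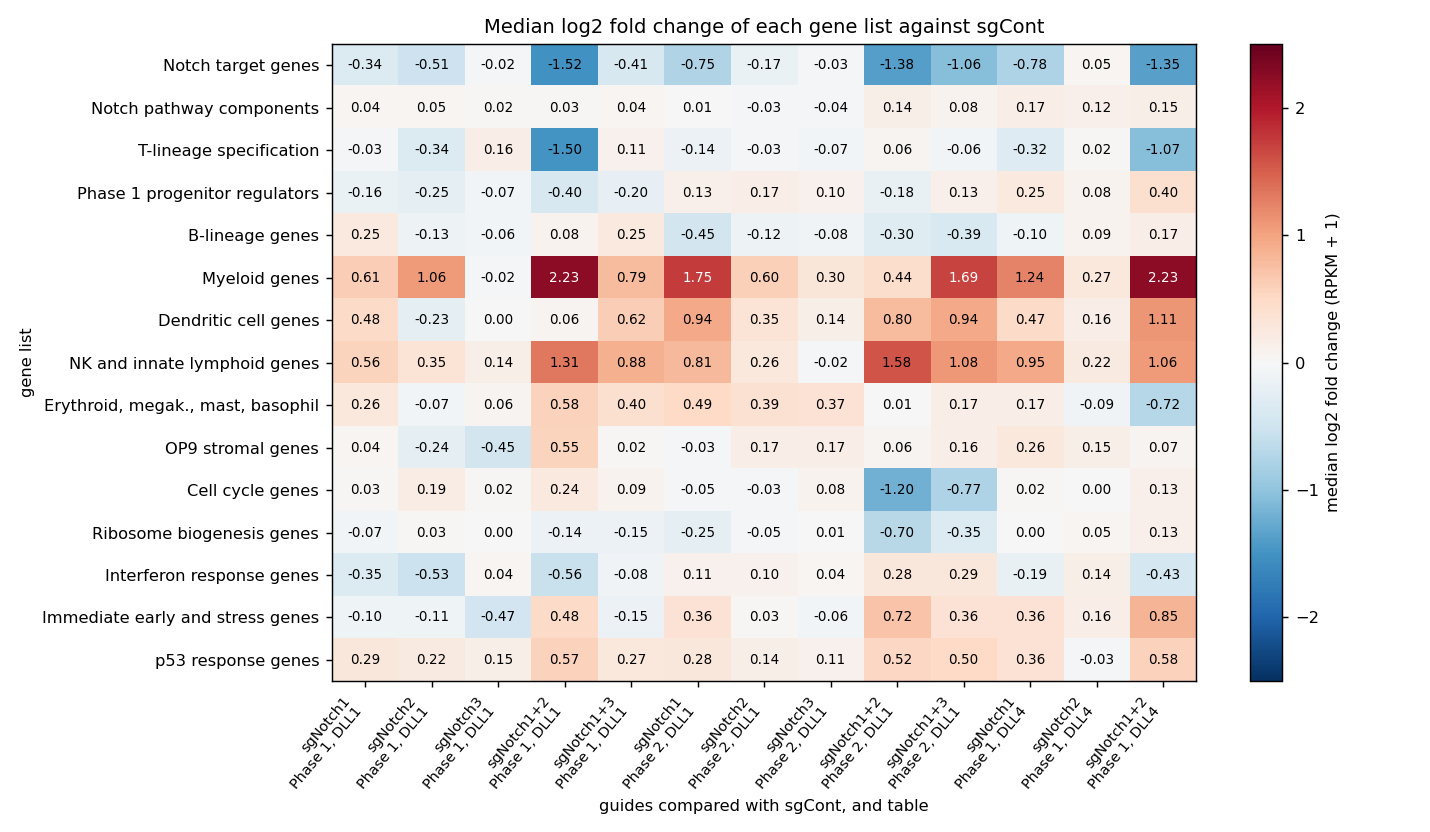
Median log2 change against sgCont of the genes of each of 15 lists (vertical) for 13 guide comparisons in the 3 sets (horizontal), with blue below 0 and red above. The Notch target list was below 0 with sgNotch1+2 in each set (-1.52, -1.38 and -1.35), and the myeloid list was highest with sgNotch1+2 in both Phase1 sets (2.23 in each).

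In the authors' deposited table for Phase1 on DLL1, adjusted p fell below 0.05 for 85 genes with sgNotch1, 244 with sgNotch2, 0 with sgNotch3, 1269 with sgNotch1+2 and 198 with sgNotch1+3. The authors' deposited table for Phase1 on DLL4 gave 611 genes with sgNotch1, 93 with sgNotch2 and 1348 with sgNotch1+2. With sgNotch2 on DLL4 all 93 rose and 0 fell there, whereas the test used here called 0 rises and 2 falls. For Phase2 on DLL1 the authors' deposited table gave 22 genes with sgNotch1, 0 with sgNotch2, 0 with sgNotch3, 369 with sgNotch1+2 and 37 with sgNotch1+3.

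Levels in sgCont cells show where each set stood in T-cell development. These are untested, since the sets were normalized separately. Bcl11b, the commitment regulator, was 3.01 ± 0.857 RPKM in Phase1 on DLL1, 50.5 ± 11.3 in Phase2 on DLL1 and 5.12 ± 1.38 in Phase1 on DLL4. Cd3g was 30.5 ± 1.78, 428 ± 13.2 and 109 ± 8.71, and Dntt, which encodes terminal transferase, was 19.5 ± 9.36, 612 ± 137 and 61.3 ± 11.9. Lmo2 was 26.4 ± 1.35, 0.19 ± 0.117 and 12.7 ± 4.2, and Cd34 was 75.5 ± 11.4, 8.54 ± 1.37 and 50.1 ± 3.7. Whether an effect of a guide differed between the sets was not tested either.

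Rbpj binding was compared between Phase1 and Phase2 on DLL1 to ask whether its sites change across commitment. The Phase1 list held 485 peaks 230 bp wide with scores of 15.0–752.1, and the Phase2 list held 4000 peaks 212 bp wide with scores of 15.0–393.7. Of the Phase1 peaks 358 overlapped a Phase2 peak (73.8%, Wilson 95% interval 69.7–77.5%), and these were 8.95% of the Phase2 list. Chance placement spread evenly over the chromosomes would give 0.316. Peaks of both lists gathered at promoters, which that expectation leaves out, so the excess over it does not measure sharing specific to Rbpj. Promoters held 43.7% of Phase1 peaks (212) and 73.6% of Phase2 peaks (2943), and intergenic sites held 31.8% and 11.7%. Of the 212 Phase1 promoter peaks 202 (95.3%) overlapped a Phase2 peak. The list lengths depend on depth and threshold, so fewer Phase1 peaks do not show fewer sites.

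The Notch targets Hes1, Dtx1 and Nrarp and the receptor gene Notch1 were assigned Rbpj peaks in both lists. The Hes1 peak lay -107 bp from the start of the gene at chromosome 16, 30065135–30065365 in Phase1 (score 22.7) and at 30065158–30065370 in Phase2 (score 66.3). A Dtx1 intron held a peak at chromosome 5, 120685738–120685968 (18.2) in Phase1 and at 120685739–120685951 (52.2) in Phase2, and Notch1 intron 1 held a peak at chromosome 2, 26502253–26502483 (16.5) in Phase1 and at 26502282–26502494 (43.8) in Phase2. The Irf8 promoter had a peak in both lists near their lowest score of 15.0, at chromosome 8, 120736285–120736515 in Phase1 (15.5) and with a score of 15.1 in Phase2. In Phase2 alone, peaks were assigned to Notch3 (chromosome 17, 32164276–32164488, score 46.9), Il2ra (chromosome 2, 11623296–11623508 and 11657753–11657965) and Myc (chromosome 15, 61985286–61985498). Other genes drawn for naming were assigned peaks as well, Bbc3 and Lgmn in both lists, and Blk, Bst1, Ccne1, Jun, Maml3, Mcm4, Mfng, Nop2, Pdgfrb, Polr1b, Tsc22d1 and Zmat3 in the Phase2 list alone.

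In Phase1 the highest scores lay in rRNA repeats rather than at these targets. The 5 highest Phase1 peaks were assigned to Pex2 (chromosome 3, 5860428–5860658, score 752.1), Txndc11 (chromosome 16, 11143973–11144203, 693.0), Filip1l (chromosome 16, 57391264–57391494, 643.7), Gm8579 (chromosome 6, 3200965–3201195, 639.1) and Myom2 (chromosome 8, 15519889–15520119, 500.3), and 9 of the 10 highest lay in rRNA repeats, which held 26 Phase1 peaks (5.4%) and 15 Phase2 peaks (0.4%). A Phase1 peak assigned to Batf3 (chromosome 1, 191120877–191121107, score 221.8) lay in an intergenic rRNA repeat 22578 bp from the start of the gene. The 5 highest Phase2 peaks were assigned to G530011O06Rik on chromosome X and Erdr1 on chromosome Y (393.7 each) and to Rn4.5s in 3 places on chromosome 6 (321.1 each). In Phase2 too, then, the highest scores lay away from the Notch targets, with the Hes1 peak at rank 78 and the higher Dtx1 peak at rank 108.

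Genes called with sgNotch1+2 were compared with uncalled genes for Rbpj peaks, and repeating this with calls from the fit with the block was decided after the data were seen. In Phase1, 54 of 1442 genes that fell had a peak (3.74%) against 242 of 8590 uncalled genes (2.82%; odds ratio 1.34, Fisher's exact adjusted p = 0.0849, or 1.38 and 0.0286 with calls from the fit with the block, 1.07 and 0.739 with peaks within 10 kb, and 1.27 and 0.362 with the upper part of the peaks by score), and 27 of 1529 genes that rose had one (1.77%; odds ratio 0.62, Fisher's exact adjusted p = 0.0777, or 0.53 and 0.0314 with peaks within 10 kb, and 0.832 and 0.258 with calls from the fit with the block). In Phase2, 4 of 11 genes that fell had a peak (36.36%) against 3041 of 11623 (26.16%; odds ratio 1.61, Fisher's exact adjusted p = 0.493, or 3.75 and 0.115 with the upper part of the peaks by score, and 1.14 and 0.739 with peaks within 10 kb). With calls from the fit with the block it was 510 of 1504 (33.91%) against 25.57% (odds ratio 1.49, Fisher's exact adjusted p = 2.51e-10). Of 31 genes that rose in Phase2, 3 had a peak (9.68%; odds ratio 0.302, Fisher's exact adjusted p = 0.0787, or 0.21 and 0.0389 with peaks within 10 kb, and 0.885 and 0.0286 with calls from the fit with the block).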

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

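The results below were singled out because the effect of a guide differed between groups, by the planned test in Phase1 on DLL4 and, chosen only after the result was seen, by comparing directions between the ligands. On DLL4 the effect of the Notch2 guide differed with and without the Notch1 guide for 15 genes. The microRNA genes Mir5136, Mir5122, Mir8099-1, Mir8099-2 and Mir8119 were among them, and genes this short gather few reads. Mir8099-1 and Mir8099-2 are listed at the same position, and Mir8119 lies within Lck, so the 15 are not all separate places. Lck was 90.6 and 104 RPKM in the sgCont libraries, 71.8 and 65.1 with sgNotch1, 105 and 105 with sgNotch2 and 31.2 and 29.4 with sgNotch1+2, which lay below the sum of the single effects by a log2 difference of -1.26. Gzma (-1.47) was 926 and 921 in sgCont, 221 and 225 with sgNotch1, 797 and 792 with sgNotch2 and 75.0 and 63.2 with sgNotch1+2. Cpa3 (-1.22) was 124 and 123, 141 and 137, 118 and 113, and 57.5 and 53.4 in the same order. The count was 31 with voom, 26 with a pseudocount of 0.1 and 0 without the filter. The count of 15 also rested on single libraries: without sgCont replicate 1 it was 1, without sgCont replicate 2 it was 26, without sgNotch2 replicate 2 it was 5, and without sgNotch1 replicate 1 or 2 or sgNotch1+2 replicate 1 or 2 it was 0.

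Among genes called with sgNotch1+2 in both Phase1 sets, 3 went opposite ways on the 2 ligands, and the difference was not tested because the sets were normalized separately. Egfl7 rose by 1.14 on DLL4 (adjusted p = 0.0448) and fell by -0.44 on DLL1 (adjusted p = 0.00539). Fads3 rose by 0.96 on DLL4 (adjusted p = 0.0235) and fell by -1.13 on DLL1 (adjusted p = 0.000677). Jak3 rose by 0.6 on DLL4 (adjusted p = 0.0373) and fell by -0.36 on DLL1 (adjusted p = 0.0314).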

How the results depend on the processing

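Median-ratio scaling, voom on approximate reads, the replicate block in the list test and in the test of peaks near genes, and shared peaks without rRNA-repeat peaks were chosen only after the data were seen; the other alternatives were planned. Count-based alternatives (other size factors, another count test and a count filter) were not run, since the tables hold RPKM. No named gene changed direction under an alternative if it passed the main test or that alternative. The direction of genes that passed neither was not compared. Of 648 gene results, 14 lost their call with a pseudocount of 0.1, 14 with 5, 89 without the filter, 12 with median-ratio scaling and 25 with voom, and the block added 29. Of 2592 gene results with a library left out, 408 lost their call and 4 gained it, where the lone library is assumed to vary like the others. For the changes below the cause was not tested.

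With the block, counts in Phase1 on DLL1 were 86 for sgNotch1 (5 without), 694 for sgNotch2 (41), 4800 for sgNotch1+2 (2971), 238 for sgNotch1+3 (27), 3962 for sgNotch1+2 against sgNotch1 (2033) and 202 for non-additive genes (0). In Phase2 they were 15 for sgNotch1 (0), 4143 for sgNotch1+2 (42) and 341 for sgNotch1+3 (0). On DLL4 replicate numbers hardly pair libraries (6 correlations of 0.04–0.26, median 0.15), and the block gave 327 for sgNotch1 (241), 2 for sgNotch2 (2), 1447 for sgNotch1+2 (1402), 188 against sgNotch1 (138) and 37 non-additive genes (15). Against sgCont in the DLL1 sets it changed no other call than those given here and in the report. In the list tests it made 8 calls and lost 3 of 195. With an estimated correlation 2 of 86 list calls were left, both of the Notch target list in Phase2 (sgNotch1 and sgNotch1+3).

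With a pseudocount of 0.1, sgNotch1 in Phase1 on DLL1 gave 0, and on DLL4 sgNotch2 gave 4 and the non-additive test 26. With 5 they were 9 for sgNotch1 and 41 for sgNotch1+3 in Phase1 on DLL1, 1 for sgNotch1+3 in Phase2 and 0 for sgNotch2 on DLL4. Without the filter, Phase1 on DLL1 gave 0 for sgNotch1, 1 for sgNotch2 and 0 for sgNotch1+3, Phase2 gave 1 for sgNotch3, 27 for sgNotch1+2, 4 for sgNotch1+3, 1 for sgNotch1+2 against sgNotch1 and 3 for sgNotch1+3 against sgNotch1, and DLL4 gave 55 for sgNotch1, 0 for sgNotch2, 62 for sgNotch1+2 against sgNotch1 and 0 non-additive genes. Median-ratio scaling gave 19 for sgNotch2 in Phase1 on DLL1, 1 for sgNotch1+3 in Phase2 and 1 for sgNotch2 on DLL4. Voom gave 0 for sgNotch1, 23 for sgNotch2 and 3 non-additive genes in Phase1 on DLL1, and 0 for sgNotch2 and 31 non-additive genes on DLL4.

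Leaving out each library in turn gave, in Phase1 on DLL1, 0–0 for sgNotch1, 0–59 for sgNotch2, 1428–3242 for sgNotch1+2, 0–0 for sgNotch1+3, 650–2546 for sgNotch1+2 against sgNotch1 and 0–76 non-additive genes. It gave 0–9 for sgNotch1+2 and 0–29 for sgNotch1+3 in Phase2. On DLL4 it gave 30–114 for sgNotch1, 0–117 for sgNotch2, 656–1149 for sgNotch1+2, 14–76 for sgNotch1+2 against sgNotch1 and 0–26 non-additive genes. The report names the libraries.

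The odds ratio of Rbpj peaks near genes that fell was 1.38 in Phase1 and 1.49 in Phase2 with calls from the block, both then past the test, and near genes that rose it was 0.832 in Phase1, not past the test, and 0.885 in Phase2, past it. With the upper part of peaks by score it was 3.75 near genes that fell in Phase2, not past the test. With peaks within 10 kb it was 0.53 near genes that rose in Phase1 and 0.21 in Phase2, both past the test, and 1.07 and 1.14 near genes that fell, not past it. The share of Phase1 peaks shared with Phase2 was 73.8%, 70.3% with a reciprocal overlap of 50%, 76.9% in the upper part by score and 76.3% without rRNA-repeat peaks. With 2 libraries per group, genes at low RPKM were measured least well.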

Other observations

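The overlap tests below and the tests of explanations were chosen only after the result was seen. The genes called with sgNotch1+2 overlapped between the ligands in Phase1 beyond chance, though most of those called on DLL1 were not called on DLL4. At a log2 change of 1 the self-test found 37% of shifted genes on DLL4 and 80.8% in Phase1 on DLL1. A call on DLL1 alone therefore does not show a difference between the ligands. Of 11256 genes tested in both sets, 1464 rose on DLL1 and 834 on DLL4, and 531 rose in both (108 expected by chance, odds ratio 17.8, Fisher's exact p = 7.06e-290). Of those that fell, 1432 on DLL1 and 550 on DLL4, 322 fell in both (odds ratio 12.2, Fisher's exact p = 3.98e-154). Genes are not independent of each other, so these p-values overstate the evidence. The counts differ between single libraries left out, as the report gives.

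In both Phase1 and Phase2 on DLL1, sgNotch1+2 lowered the Notch target Dtx1, the receptor gene Notch3, the T-cell receptor gene Cd3g and the stem-cell regulator Erg, with Mdfi, Fbp1 and Myl4. It raised the chemokine-receptor genes Ccr2 and Ccr5, the NK receptor gene Klrd1 and the p53-response gene Ccng1. Of 11029 genes tested in both, 10 fell in both (1.42 expected, odds ratio 68.2, Fisher's exact p = 1.18e-08) and 10 rose in both (3.25 expected, odds ratio 4.4, Fisher's exact p = 0.000716), and 0 went opposite ways. These calls come from the fit without the block, and with the block, which the pairing of the replicate numbers in these sets allows, 4143 genes passed in Phase2 in place of 42. Without the block the 42 became 0 without sgCont replicate 1, sgCont replicate 2 or sgNotch1+2 replicate 1 and 9 without sgNotch1+2 replicate 2.

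Myeloid genes rose with sgNotch1+2 in Phase1 on DLL1, with a list median of 2.23. A lower share of T-lineage cells could raise every other cell type alike. Of 4 other lineage lists, 3 lay below the myeloid median by more than its spread of 1.02 (B-lineage 0.08, dendritic 0.06, erythroid and mast 0.58). The NK list (1.31) lay within it. B, NK, erythroid and dendritic cells were depleted at the start, as were granulocytes and macrophages, and genes near 0 RPKM change little on the log2(RPKM + 1) scale. The erythroid and mast list also holds genes that differed between replicates. These medians therefore cannot decide the question. RPKM scaling by a few abundant transcripts could also raise the myeloid genes, yet with median-ratio scaling 15 of the 15 called myeloid genes still passed, at a list median of 2.25, which argues against it. What stays open is a lower share of T-lineage cells, a change in cell fate, or growth of myeloid cells left after the starting depletion of granulocytes and macrophages, and the design cannot separate these.

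Beta-globin RNA fell with sgNotch1+2 in Phase1. Its sum over the gene copies was 1890 and 1240 RPKM in the sgCont libraries of Phase1 on DLL1 and 45.9 and 44.3 with sgNotch1+2, and on DLL4 it was 1950 and 1610 against 200 and 125. In Phase2 it was 337 and 111 in sgCont and 70.8 and 88.2 with sgNotch1+2. Erythroid cells, depleted at the start with TER-119, could be the source, but they carry alpha-globin as well. The lowest ratio of beta to alpha in a Phase1 sgCont library was 30.3. This ratio is uncertain, since the beta sum may count shared reads more than once and shared alpha reads may be undercounted. On DLL1 alpha was 0.654 and 40.9 RPKM in the sgCont libraries and 0.478 and 42.5 with sgNotch1+2. On DLL4 it was 0.745 and 0.301 against 5.9 and 3.72. Alpha did not fall as beta did. In replicate 2 on DLL1, where alpha lay well above 0, it stayed level while beta fell from 1240 to 44.3. In the other Phase1 sgCont libraries alpha was near 0 (0.301–0.745) beside beta sums of 1610–1950. These values argue against erythroid cells as the main source of beta-globin in Phase1 sgCont cells. A smaller erythroid share stays open, since shared alpha reads may be undercounted. Reads moving between beta-globin copies could fake a fall of 1 copy, but the beta-globin sum itself fell to at most 12.4% of the lowest sgCont library, which argues against that. Beta-globin RNA made by the progenitors themselves stays open as a hypothesis, and which copy is expressed cannot be read.

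Mast-cell and basophil genes were higher in replicate 1 of Phase1 on DLL1. A single odd library could give this in sgNotch1+2, where Mcpt8 was 1210 RPKM in replicate 1 and 15.0 in replicate 2, Prss34 was 1080 and 3.62, and Gata2 was 107 and 1.73, but replicate 1 was higher in 5 of 5 other groups too (median ratios of 7.43 in sgCont, 13.5, 16.3, 7.22 and 14.9 in the others), which argues against a difference carried by that library alone. The ratio in sgNotch1+2 was 76.8, and its excess over the other groups stays open. More mast cells or basophils in replicate 1 stay open too: 7 of 7 marker genes were higher in replicate 1 in at least 5 of the 6 groups, but this restates the pattern and does not test that explanation. The starting depletion used no marker specific to mast cells or basophils, though basophils can carry CD11b, which it did use. Why replicate 1 would hold more was not tested.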
